A study of Mus musculus with 8 samples.

How the data were processed

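Single-cell RNA sequencing (10x Genomics 3' chemistry) was run on mouse embryonic stem cells under retinoic acid (RA) signalling. The series holds 8 libraries, 1 per group. Count matrices were used for 3 wild-type libraries: cells at 0 h, cells at 24 h without RA and cells at 24 h with 2 uM RA. For the other 5 libraries, all at 24 h with RA, the barcode and gene lists were used and expression was not analysed here. These were a wild type and a double knockout of one series (RARX), and a wild type, a Cyp26a1 knockout and a Hoxb4 knockout of another. Per the labels, the cells were grown on gelatin in serum with LIF and the inhibitors PD0325901 and CHIR99021. The treatment text gives removal of LIF and the inhibitors, or addition of RA, as the ways differentiation was started, and leaves open whether the RA cells kept LIF and the inhibitors. The library without RA is read here as cells after that removal, so the libraries at 24 h can differ by the medium as well as by RA.

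The values are UMI counts per gene and cell barcode, deposited by the authors as filtered Cell Ranger matrices on mm10 (version not given in the sources used here), per the submitters' processing notes. The 3 matrices held whole numbers for 32285 genes, with at least 500 UMIs in each barcode. The libraries at 0 h, 24 h without RA and 24 h with RA held 7351, 8373 and 10286 barcodes and 132049868, 84439072 and 117693838 UMIs. Between 0.177% and 0.334% of barcodes were shared by a pair of libraries, or 13 to 28 barcodes. Of the gene identifiers, 32158 (99.61%) were found in the GENCODE vM21 annotation of GRCm38, 31436 of them with the same symbol, and gene positions were taken from it.

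Cells with at least 1000 genes detected and under 10% mitochondrial UMIs were kept: 6492 at 0 h, 6210 without RA and 7047 with RA. The filter removed 11.7%, 25.8% and 31.5% of barcodes, which held 1.01%, 2.78% and 2.64% of the UMIs. Most of the removed barcodes had few genes (633, 1785 and 3067), and 226, 378 and 172 failed only on mitochondrial UMIs. The kept cells had a median of 18420, 12750 and 15560 UMIs and 4677, 3961 and 4353 genes, with medians of 2.43%, 2.48% and 2.28% mitochondrial and 23.9%, 21.8% and 23.6% ribosomal protein UMIs. The 50 most abundant genes took 21.0%, 19.7% and 20.5% of the UMIs. Doublet scores were computed per library with Scrublet as implemented in scanpy, whose own threshold marked 0, 1 and 0 cells, so doublets were kept.

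UMIs were summed over the kept cells of a library (130720079, 82089554 and 114589828 UMIs) and expressed as CPM (UMI counts scaled to a common library total). Ratios were taken as log2((CPM + 1)/(CPM + 1)). A gene was counted as higher or lower when it had at least 20 CPM in one of the 2 libraries compared and differed at least 2-fold on that scale. Folds in the text are ratios of CPM without the added 1, with exact (Clopper-Pearson) 95% intervals of the ratio of 2 counts, and intervals of a CPM are exact Poisson intervals. They hold counting error only. With 1 library per group there is no test, no replicate check and no pairing of samples, and a difference between groups includes any difference between cultures or library preparations. A count of 3 UMIs corresponds to 0.0229, 0.0365 and 0.0262 CPM, and a fold against a library with 0 UMIs is given as a bound against 3 counts over the library.

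Gene groups were 28 fixed lists: naive pluripotency, general pluripotency, formative or primed epiblast, RA pathway, the 4 Hox clusters, Hox cofactors and caudal genes, primitive or extraembryonic endoderm, primitive streak or mesendoderm, neural ectoderm, trophoblast, fibroblast or feeder, 2-cell-like state, germline genes, FGF-ERK targets, Wnt targets, LIF-STAT3 targets, DNA methylation machinery, chromatin looping and enhancer cofactors, glycolysis, oxidative phosphorylation, epithelial-mesenchymal genes, p53 targets, stress and dissociation, S phase, and G2 and M phase. A list gene was measured when it had at least 1 CPM in any of the 3 libraries. The list's median was set against 10000 random lists of the same size matched on expression in 20 bins, and its percentile among them describes these libraries only. Aldoa and Ddit3 (2 identifiers per symbol) and Zscan4a (absent from the matrices) were left out. Results for some genes are not reported here.

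For each comparison, the named genes were the 12 with the highest and the 12 with the lowest log2 ratio among genes with at least 20 CPM, leaving out mitochondrial and ribosomal protein genes and gene models known only by clone or accession names. Also named were up to 2 measured members of each list with the highest and 2 with the lowest ratio, Hox genes, 30 genes whose share of cells was planned, and the 10 leading genes of each cluster. This rule, the lists, the filter, the thresholds and the alternatives other than those named below as added were set before the data were examined. Other list members are named as examples and were chosen after their values were seen, as were the shares of cells for Stra8, Meg3, Rian, Dazl, Cidea, Aqp3 and Zscan4d.

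The share of cells with at least 1 UMI of a gene was taken after thinning each cell to 5000 UMIs without replacement, with exact 95% binomial intervals. This used 6283, 5547 and 6697 cells and left out 209, 663 and 350 with fewer UMIs. The cells used had a median of 18634, 13386 and 15858 UMIs before thinning. For pairs of genes, the number of cells with both was divided by the number expected from the 2 shares. No ratio is given where fewer than 5 cells were expected, except for Meg3 with Rian in the RA library (2.598 expected). Each library was clustered alone (Leiden; 2000 variable genes, 30 principal components, 15 neighbours, resolution 0.5). A cluster was described by its leading genes against the other cells of the library, and clusters with low UMI counts were left unnamed. Genes that build a cluster also separate it, so their folds between clusters describe the cluster and are no separate result.

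Counts were simulated from the pooled profile of each pair of libraries with Poisson counting error only, without variation between cultures or preparations. In each of the 3 comparisons, 100 of 100 genes set 4-fold apart and 0 of 100 set 1.5-fold apart were called. There were 0 calls among 5952, 5935 and 6044 genes without a difference. This checks the calculation and gives no error rate for differences between these libraries. The counting interval held the true ratio for 96.34%, 95.94% and 95.87% of genes, in the order no RA against 0 h, RA against 0 h and RA against no RA. Of 200 random lists, 95.5%, 94.0% and 96.0% fell in the central 95%. Thinning of 300 simulated cells gave a mean share of 20.282% over 4504 genes where 20.270% was expected, and 2000 independent pairs had a mean ratio of 1.008.

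The alternatives were scaling by TMM factors, totals without mitochondrial and ribosomal protein genes, means of per-cell CPM, all deposited barcodes, a stricter cell filter (2000 genes, 5% mitochondrial UMIs), pseudocounts of 0.1 and 5 CPM, floors of 5 and 50 CPM or none beyond 1 CPM, list members measured at 10 CPM, thinning to 3000 or 8000 UMIs or none, resolutions of 0.3 and 1, and variable genes without the cell-cycle lists. Removal of the 6% of cells with the highest doublet score (390, 373 and 423 cells) and variable genes without the RA, Hox, caudal, endoderm and share genes were added after the data were seen. TMM moved the median of all genes by -0.141 (no RA against 0 h), -0.134 (RA against 0 h) and 0.007 (RA against no RA) on the log2 scale.

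Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.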

Results

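Wild-type mouse embryonic stem cells were compared under 3 conditions, with 1 library each: 6492 cells at 0 h, 6210 cells at 24 h without RA and 7047 cells at 24 h with 2 uM RA. The libraries held a median of 18420, 12750 and 15560 UMIs per cell, and 14927 genes reached 1 CPM in at least 1 of them. The intervals given hold counting error only, and differences between cultures or library preparations cannot be separated from differences between conditions. The 5 further RA libraries of the series held 14491 (RARX series wild type), 14446 (double knockout), 16571 (wild type of the Cyp26a1 and Hoxb4 series), 13951 (Cyp26a1 knockout) and 15297 (Hoxb4 knockout) barcodes, and their expression was not analysed here.

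At 24 h without RA, genes of the formative epiblast were higher and several naive pluripotency genes were lower than at 0 h. Otx2, a homeobox factor of the formative epiblast, was at 95.3 CPM against 2.11 at 0 h, or 45.1-fold higher (95% interval 40.0 to 51.1), and the POU factor Pou3f1 was 20.9-fold higher (19.1 to 22.9). Tfcp2l1, a factor of naive pluripotency, was 6.92-fold lower (6.71 to 7.13), at 54.3 against 376 CPM, and Nanog was 2.68-fold lower (2.62 to 2.75). Socs3, a feedback inhibitor induced by STAT3, was 11-fold lower (9.76 to 12.4). Of 6521 genes with at least 20 CPM in either library, 239 were at least 2-fold higher and 100 at least 2-fold lower, 60 and 22 of them at least 4-fold, and 94.8% lay within 2-fold. With TMM scaling the split was 181 higher and 144 lower, so the excess of higher genes (70.5% of calls, 55.7% with TMM) depends on the scaling.

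The 12 genes with the highest ratios without RA included Enpp3 (28.7 against 0.229 CPM, 125-fold), the epithelial transcription factor Grhl2 (57.5 against 1.29, 44.4-fold), Gadd45g (54.8 against 3.89), the imprinted growth inhibitor Cdkn1c (110 against 10.3) and the imprinted gene Peg10 (69.5 against 6.95). Nell1, Sned1, Slc7a7, Emb and the Wnt effector Lef1 were 13.8-, 11.1-, 9.70-, 8.76- and 8.91-fold higher. Those with the lowest ratios included the channel gene Trpm1 (0.658 against 40.7 CPM, 61.9-fold lower), the caudal factor Cdx1 (0.987 against 38.9, 39.4-fold lower, 31.7 to 49.7), the laminin gene Lama1 (1.67 against 36.4) and Pgc (1.85 against 29.2). Sh2d4b, Tfap2c, Kit, Lrrc34 and Epp13 were 10.7-, 9.88-, 6.61-, 6.36- and 6.22-fold lower.

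Among the fixed lists, 11 of 12 formative or primed epiblast genes were at least 2-fold higher without RA than at 0 h (median log2 ratio 2.27). The growth factor Fgf5 (4.02 against 0.061 CPM, 65.7-fold, 32.9 to 153), the de novo DNA methyltransferases Dnmt3a (144 against 18.3) and Dnmt3b (169 against 56.5), Zic2 (34.3 against 4.94), Fgf15 (12.7 against 1.03) and Sox11 were among them, and Cdh2 (4.68 against 4.51) was the member that differed less. Of 15 naive pluripotency genes, 6 were lower, 1 higher and 8 neither (median -0.91): Nanog, Klf4 (67.1 against 190 CPM), Tfcp2l1, Tbx3 (81.3 against 258), Nr5a2 (30.3 against 90.1) and Fbxo15 (32.4 against 97.9) were lower, and Nr0b1 was 2.04-fold higher. Of 10 general pluripotency genes, 3 were higher, 1 lower and 6 neither (median 0.49), with Utf1 at 658 against 257 CPM, Dppa2 at 113 against 52.4, Sox2 at 342 against 292 and Pou5f1 2.78-fold lower at 139 against 388. The medians of the formative and naive lists lay above and below those of all 10000 random lists.

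Of 8 LIF-STAT3 targets, 3 were lower and 5 neither (median -0.53), with Socs3, Stat3 (14.8 against 52.2 CPM) and Bcl3 (3.40 against 20.9) lower, and of 11 FGF-ERK targets 5 were higher and 6 neither (median 0.82), with Dusp6 at 30.5 against 7.78, Dusp4 at 11.4 against 1.13 and Spry4 at 61.8 against 21.0 CPM. The 9 Wnt targets went both ways: Lef1 was higher, Sp5 was 80.6-fold lower (43.7 to 168) and 7 were neither (median -0.02). Of 9 DNA methylation genes, 3 were higher and 6 neither (median 0.40), with the cofactor Dnmt3l at 272 against 75.8 CPM. Of 11 glycolysis genes, 3 were higher (Pfkp, Pgk1 and Slc2a1) and 8 neither (median 0.49). The adhesion gene Epcam was 5.44-fold higher (5.25 to 5.64) and the other 9 epithelial-mesenchymal genes were neither (median 0.03). Of 9 p53 targets, Pmaip1 was 7.5-fold higher, the cell-cycle inhibitor Cdkn1a 3.16-fold lower and 7 were neither (median -0.34). Of 7 stress and dissociation genes, Gadd45a was higher and 6 neither (median -0.07), and of 11 germline genes Dazl and Mael were higher and 9 neither (median 0.70).

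With 1 CPM added to both libraries, most RA pathway, Hoxa and Hoxb genes were within 2-fold of 0 h without RA. On that scale a gene under 1 CPM at 0 h, such as Hoxa5 (0.099, and 0.195 without RA), could not be called lower. Of 19 RA pathway genes, the receptor gene Rarg (115 against 34.6 CPM) and the RA-binding protein gene Crabp2 (6.05 against 2.43) were higher and 17 neither (median 0.05). Of 8 Hoxa genes 0 were higher or lower (median -0.03), of 9 Hoxb genes 1 (Hoxb9, 2.08 against 8.12 CPM) was lower and 8 neither (median -0.10), of 2 Hoxc genes Hoxc13 was lower (0.865 against 5.89) and 1 neither (median -1.36), and 0 Hoxd genes reached 1 CPM in any library. Of 8 Hox cofactors and caudal genes, 2 were higher, Pbx3 among them, Cdx1 was lower and 5 were neither (median 0.42). Of 10 endoderm genes, Col4a1 (8.69 against 2.80 CPM) was higher, Lama1 lower and 8 neither (median 0.09). Gsc was lower and 1 neither among 2 primitive streak genes (median -0.50), Ascl2 higher and 2 neither among 3 trophoblast genes (median -0.16), and Zscan4d higher (1.65 against 0.191 CPM) and 2 neither among 3 genes of the 2-cell-like state (median 0.74). The Zscan4d UMIs lay in 9 of 6210 cells without RA and 6 of 6492 at 0 h, so that difference rests on few cells. In the neural ectoderm (5 genes), fibroblast (2), chromatin looping (14), oxidative phosphorylation (14), S phase (10) and G2 and M phase (10) lists, 0 genes were higher or lower, with medians of 0.03, 0.43, 0.07, -0.18, 0.14 and 0.11. The medians of the RA pathway, endoderm, neural ectoderm, looping, epithelial-mesenchymal, S phase and G2 and M phase lists changed sign with TMM scaling, and those of the Wnt and stress lists with means of per-cell CPM, so no direction is given for them.

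**Figure D1:**
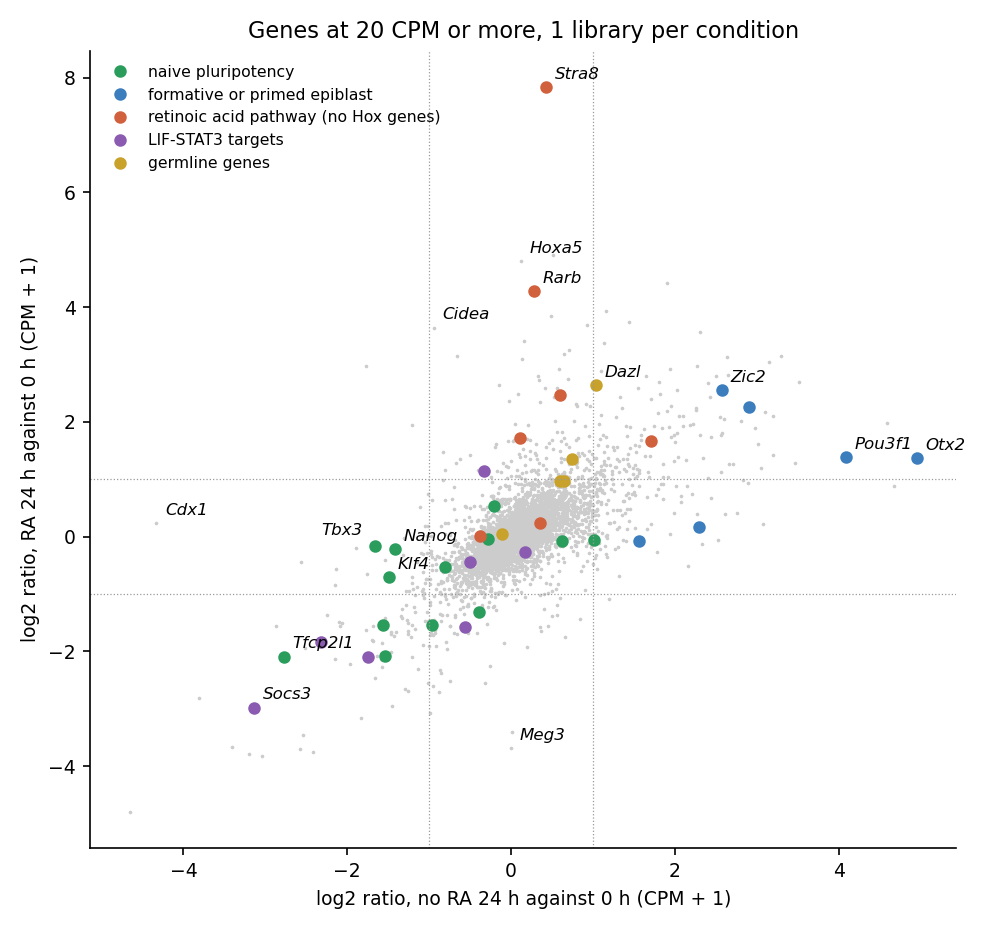
Log2 ratios of genes with at least 20 CPM, at 24 h without RA against 0 h (x axis) and at 24 h with RA against 0 h (y axis), 1 point per gene, with genes of 5 lists coloured and dotted lines at 2-fold. Otx2 was at 95.3 CPM without RA and 7.05 with RA, and Stra8 at 1.72 and 460.

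At 24 h with RA, 9 of 19 RA pathway genes, 8 of 8 Hoxa genes and 4 of 9 Hoxb genes were higher than at 0 h, and 5 of 15 naive pluripotency genes were lower. Stra8, a gene named for its stimulation by RA and needed for meiotic entry, was at 460 against 1.02 CPM, or 453-fold higher (382 to 541). Cyp26a1, which encodes an enzyme that degrades RA, was at 11.1 CPM against 0.023, a ratio of 483 (165 to 2347) on 3 UMIs at 0 h, and the receptor gene Rarb was 39.2-fold higher (32.7 to 47.3). Hoxa5 was 298-fold higher (174 to 561), at 29.7 against 0.099 CPM. Nanog was at 236 against 276 CPM and Pou5f1 at 332 against 388. Of 6519 genes with at least 20 CPM, 270 were at least 2-fold higher and 160 lower, 69 and 37 of them at least 4-fold. With TMM scaling the split was 217 higher and 219 lower, so the excess of higher genes (62.8% of calls, 49.8% with TMM) depends on the scaling.

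The genes with the highest ratios against 0 h also included Ankrd44 (88.2 against 1.96 CPM, 45.1-fold), Nhs (67.8 against 2.20), the ERK phosphatase gene Dusp9 (137 against 8.0), Greb1l (30.3 against 1.17), Cidea (95.3 against 6.69) and Fbp2 (56.0 against 4.36). Clgn, Gca and Tnfsf12 were 17.6-, 17.9- and 16.9-fold higher. Among those with the lowest ratios were the imprinted noncoding RNAs Meg3 (5.14 against 77.8 CPM, 15.1-fold lower, 13.9 to 16.5) and Rian (3.61 against 47.6, 13.2-fold lower, 11.9 to 14.6), Trpm1 (0.506 against 40.7), Pglyrp1 (3.08 against 53.8) and the kinase gene Sgk1 (19.1 against 154). Sh2d4b, Lrrc34, Pgc, Epp13, Dpys and Socs3 were 17.9-, 15.2-, 21.3-, 12.5-, 13.2- and 9.57-fold lower.

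Of 19 RA pathway genes, 9 were at least 2-fold higher with RA than at 0 h and 10 neither (median 0.74, above all 10000 random lists). Beside Stra8, Cyp26a1 and Rarb these included Rarg (113 against 34.6 CPM), the retinol-binding protein receptor gene Stra6 (5.96 against 0.459), the retinal reductase gene Dhrs3 (13.2 against 2.11), the nuclear receptor corepressor gene Nrip1 (44.3 against 12.7) and Zfp703 (6.42 against 0.444). Another RA-degrading enzyme gene, Cyp26b1, was at 1.05 CPM against 0.222. Cyp26a1 lies on chromosome 19 (37697798 to 37701536) and Stra8 on chromosome 6 (34920163 to 34939344).

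The 8 measured Hoxa genes were higher with RA (median 2.18). Among them, Hoxa2, Hoxa3 and Hoxa4 were at 3.74, 8.11 and 3.38 CPM against 0.283, 0.291 and 0.076 at 0 h, and Hoxa7 and Hoxa9 at 10.7 and 1.92 CPM against 1.09 and 0.138. Hoxa5 was the member with the highest level. Of 9 Hoxb genes, 4 were higher and 5 neither (median 0.93): Hoxb2 (5.71 against 0.015 CPM, a ratio of 373, 103 to 3087), Hoxb3 (1.26 against 0.031), Hoxb4 (2.65 against 0.023, a ratio of 116, 39.2 to 564) and Hoxb5 (2.56 against 0.015). These 4 had 2 to 4 UMIs at 0 h. Hoxb1 was under 1 CPM, at 0.777, and Hoxb9 was at 3.97 against 8.12. Of 2 Hoxc genes, Hoxc13 was lower (0.873 against 5.89) and 1 neither (median -1.06). The Hoxa genes lie on chromosome 6, with Hoxa5 from 52201754 to 52204587, and the Hoxb genes on chromosome 11, with Hoxb4 from 96318267 to 96321638. Of 8 Hox cofactors and caudal genes, 4 were higher, among them Pbx3, Meis1 and Meis2 (48.9 against 15.3 CPM), and 4 neither (median 0.98).

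**Figure D2:**
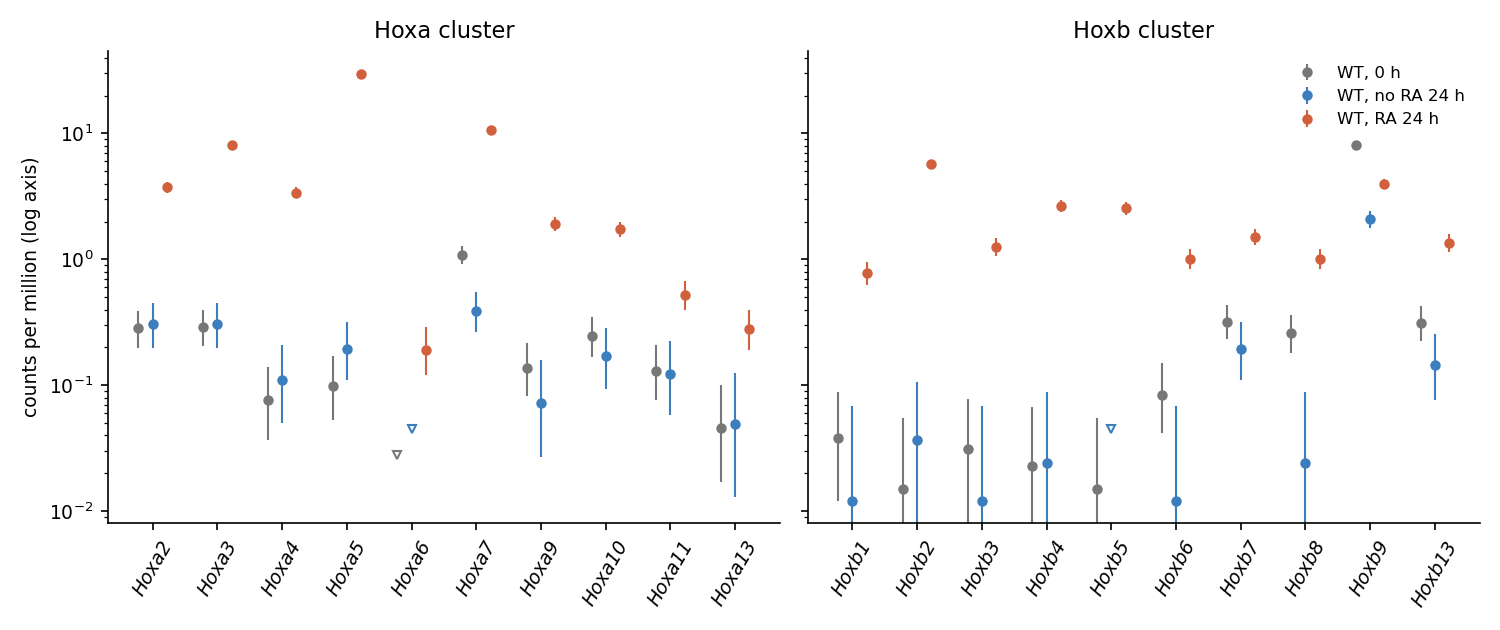
CPM of Hoxa and Hoxb genes (log axis) at 0 h, at 24 h without RA and at 24 h with RA, with exact Poisson 95% intervals and open triangles for the upper bound where 0 UMIs were counted. Hoxa5 was at 0.099, 0.195 and 29.7 CPM and Hoxb2 at 0.015, 0.037 and 5.71.

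Of 15 naive pluripotency genes, 5 were lower with RA than at 0 h and 10 neither (median -0.68): Tfcp2l1 (87.3 against 376 CPM), Nr5a2 (20.6 against 90.1), Klf2 (142 against 417), Tcl1 (12.8 against 33.3) and Fbxo15 (33.1 against 97.9). Esrrb was at 96.7 against 140 CPM, Klf4 at 116 against 190, Tbx3 at 232 against 258 and Zfp42 at 711 against 733. Of 10 general pluripotency genes, Dppa2 was higher (232 against 52.4) and 9 neither (median 0.18). Of 12 formative genes, Otx2, Pou3f1 (12.3 against 4.11), Dnmt3a (91.7 against 18.3), Zic2 (33.8 against 4.94) and Sox3 were higher and 7 neither (median 0.86), with Dnmt3b at 53.3 against 56.5 and Fgf5 at 0.34 against 0.061. Dnmt3a was the 1 higher gene of 9 DNA methylation genes, with 8 neither (median 0.17).

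Of 11 germline genes, 7 were higher with RA than at 0 h and 4 neither (median 1.46), with Dazl at 39.0 against 5.42 CPM, Taf7l at 10.8 against 1.16, Sycp1 at 8.74 against 1.39 and Mael at 9.32 against 1.42. The 3 measured genes of the 2-cell-like state were higher (median 1.74), with Zscan4d at 4.77 against 0.191 CPM and Zscan4c at 2.78 against 0.130. The Zscan4d UMIs lay in 71 of 7047 RA cells and 6 of 6492 cells at 0 h. Of 10 endoderm genes, Gata6 (6.69 against 0.268 CPM, 25-fold, 17.8 to 36.1), Col4a1 (16.4 against 2.80) and Col4a2 were higher, Lama1 (4.34 against 36.4) lower and 6 neither (median 0.55). Of 11 FGF-ERK targets, 6 were higher, 1 lower and 4 neither (median 1.04), with Phlda1 at 62.0 against 7.99 CPM, Dusp6 at 31.7 against 7.78 and Spry2 at 18.0 against 45.2. Of 8 LIF-STAT3 targets, Socs3, Stat3 (11.4 against 52.2), Junb (6.87 against 22.5) and Bcl3 were lower, Pim1 (171 against 76.7) higher and 3 neither (median -1.01). Of 9 Wnt targets, Lgr5 was higher, Axin2 (5.14 against 14.8) and Sp5 (0.079 against 9.82) lower and 6 neither (median -0.41).

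Of 9 p53 targets, Pmaip1 was higher with RA than at 0 h (23.8 against 2.56 CPM), Cdkn1a (26.4 against 115), Bbc3 and Btg2 lower and 5 neither (median -0.78). Of 10 epithelial-mesenchymal genes, Epcam was higher (60.7 against 29.5), Vim lower (86.8 against 175) and 8 neither (median 0.34), of 7 stress genes Gadd45a was higher, Fos lower and 5 neither (median 0.33), and of 11 glycolysis genes the glucose transporter gene Slc2a1 was higher (235 against 76.7) and 10 neither (median 0.16). Of 2 primitive streak genes, Gsc was lower and 1 neither (median -0.44). In the neural ectoderm, trophoblast, fibroblast, looping, oxidative phosphorylation, S phase and G2 and M phase lists, 0 genes were higher or lower, with medians of -0.24, 0.73, 0.32, -0.07, -0.10, -0.06 and 0.16, of which the fibroblast median changed sign with totals without mitochondrial and ribosomal protein genes. The insulator gene Ctcf was at 205 against 193 CPM.

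**Figure D3:**
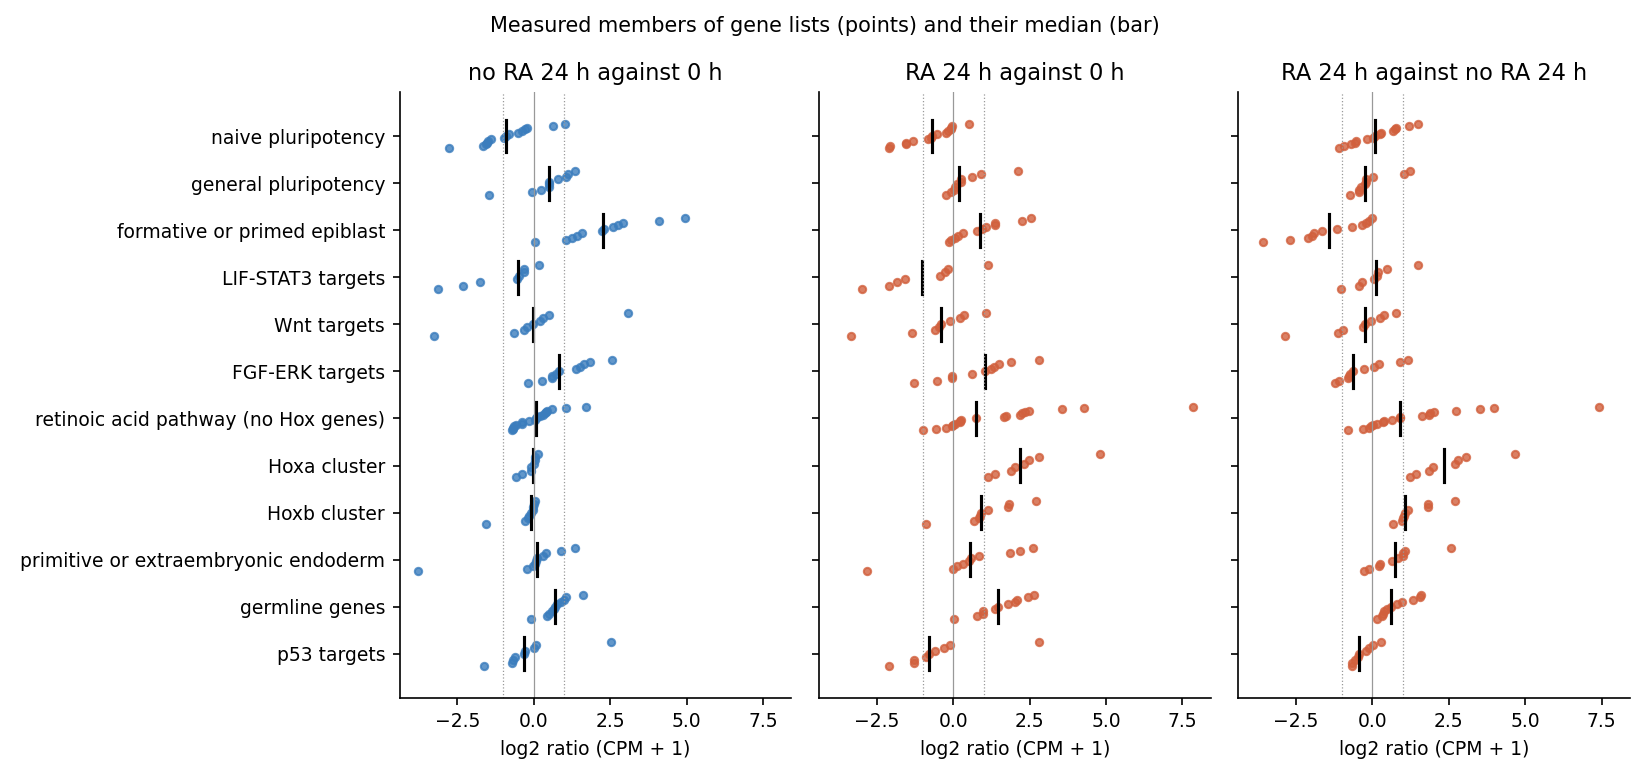
Log2 ratios of the measured members of 12 gene lists (points) in the 3 comparisons, with the list's median as a black bar. The formative list had medians of 2.27 (no RA against 0 h), 0.86 (RA against 0 h) and -1.41 (RA against no RA), and the Hoxa list -0.03, 2.18 and 2.35.

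Between the cells at 24 h, 8 of 19 RA pathway genes, 8 of 8 Hoxa genes and 6 of 9 Hoxb genes were higher with RA than without, 7 of 12 formative genes were lower, and Nanog and Pou5f1 were higher. Stra8 was 268-fold higher with RA (227 to 319), Hoxa5 152-fold (93.5 to 266), Rarb 27.0-fold (22.4 to 33.0) and Cyp26a1 a ratio of 182 (77.8 to 562) on 5 UMIs without RA. Otx2 was 13.5-fold lower (12.6 to 14.5), at 7.05 against 95.3 CPM, and Pou3f1 6.98-fold lower. Nanog was at 236 against 103 CPM (2.30-fold higher, 2.24 to 2.36) and Pou5f1 at 332 against 139 (2.38-fold higher). Of 6538 genes with at least 20 CPM, 119 were at least 2-fold higher and 127 lower, 30 and 24 of them at least 4-fold.

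The other genes with the highest ratios were the water channel gene Aqp3 (52.6 against 0.999 CPM, 52.7-fold, and 5.83 at 0 h), Cdx1 (45.8 against 0.987, 46.4-fold, 37.3 to 58.6), Cidea (95.3 against 3.00, 31.8-fold), Ankrd44 (88.2 against 3.23), the kinase gene Aurkc (35.1 against 1.60), Calcoco2 (165 against 17.7) and Dmrt1 (43.3 against 4.69), with Greb1l and Fbp2 14.8- and 11.2-fold higher. Cdx1, which was 39.4-fold lower without RA than at 0 h, was at 45.8 CPM with RA and 38.9 at 0 h. Those with the lowest ratios were Grhl2 (3.24 against 57.5 CPM, 17.7-fold lower), Meg3 (5.14 against 77.8, 15.1-fold lower, 13.9 to 16.5), Rian (3.61 against 48.1), Lef1 (17.1 against 130), Enox1 (44.6 against 273), the MYC-family gene Mycn (7.19 against 42.2) and the sulfatase gene Sulf1 (8.04 against 56.8). Enpp3, Aass and Ror1 were 7.43-, 6.39- and 6.2-fold lower. Meg3 and Rian had like levels at 0 h and without RA (77.8 and 77.8, 47.6 and 48.1 CPM).

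Of 19 RA pathway genes, 8 were higher with RA than without and 11 neither (median 0.90). Rarg, higher in both libraries at 24 h than at 0 h, was at 113 and 115 CPM and so was not among the 8. Zfp703 was 58.6-fold higher (30.7 to 129), Stra6 6.61-fold and Dhrs3 5.19-fold. The 8 measured Hoxa genes were higher (median 2.35), with Hoxa3 26.6-fold (17.9 to 41.4) and Hoxa7 27.4-fold higher. Of 9 Hoxb genes, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb7 and Hoxb13 were higher and 3 neither (median 1.07), Hoxb2 by a ratio of 156 (53.2 to 759) and Hoxb5 at least 70.0-fold, with 0 UMIs without RA. Of 8 cofactors and caudal genes Cdx1 was higher and 7 neither (median 0.35), and of 2 Hoxc genes 0 were higher or lower (median 0.30).

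Of 12 formative genes, 7 were lower with RA than without and 5 neither (median -1.41, below all 10000 random lists): Fgf5 (0.34 against 4.02 CPM, 11.8-fold lower, 8.46 to 16.9), Otx2, Pou3f1, Dnmt3b (53.3 against 169), Fgf15 (2.51 against 12.7), Sall2 and Sox11 (5.73 against 28.2). Zic2 was at 33.8 and 34.3 CPM. Of 15 naive pluripotency genes, Nanog and Tbx3 (232 against 81.3) were higher, Nr0b1 (50.0 against 106) lower and 12 neither (median 0.09), with Tfcp2l1 at 87.3 against 54.3, Klf4 at 116 against 67.1 and Klf2 at 142 against 212. Of 10 general pluripotency genes, Pou5f1 and Dppa2 (232 against 113) were higher and 8 neither (median -0.24). Dnmt3b was the 1 lower gene of 9 DNA methylation genes (median -0.44).

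Of 11 germline genes, Dazl (39.0 against 12.2 CPM), Taf7l and Sycp1 were higher and 8 neither (median 0.62), and the 3 measured genes of the 2-cell-like state were higher (median 1.00). Few cells carried the latter, with Zscan4d UMIs in 71 of 7047 cells with RA and 9 of 6210 without. Of 10 endoderm genes, 3 were higher, among them Gata6 (22.9-fold, 15.3 to 35.9), and 7 neither (median 0.74). Of 11 FGF-ERK targets, Phlda1 (62.0 against 27.2) was higher, Spry2 (18.0 against 39.8) and Dusp4 (4.32 against 11.4) lower and 8 neither (median -0.62). Of 9 Wnt targets, Lef1 and Axin2 (5.14 against 12.5) were lower and 7 neither (median -0.25). Of 8 LIF-STAT3 targets, Pim1 (171 against 60.6) was higher, Junb (6.87 against 15.0) lower and 6 neither (median 0.11), with Socs3 at 4.08 and 3.56 CPM. Epcam was lower (60.7 against 161) with 9 of 10 epithelial-mesenchymal genes neither (median 0.16), Pfkp lower (137 against 281) with 10 of 11 glycolysis genes neither (median -0.10), and Fos lower (6.81 against 15.7) with 6 of 7 stress genes neither (median 0.44). In the primitive streak, neural ectoderm, trophoblast, fibroblast, looping, oxidative phosphorylation, p53, S phase and G2 and M phase lists, 0 genes were higher or lower, with medians of 0.06, 0.01, -0.36, -0.11, -0.14, 0.08, -0.43, -0.22 and -0.09. The fibroblast median changed sign with totals without mitochondrial and ribosomal protein genes, and the neural median with means of per-cell CPM. The looping list holds Ctcf (205 against 200 CPM), the cohesin genes and Yy1.

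At 5000 UMIs per cell, 78.1% of the RA cells (77.1 to 79.1) had a Stra8 UMI, against 0.35% at 0 h and 0.883% without RA. Rarb was found in 14.9% (14.0 to 15.7), Hoxa5 in 12.9% (12.1 to 13.7), Cyp26a1 in 4.58% (4.10 to 5.11), Hoxa3 in 3.94%, Hoxb2 in 2.42%, Hoxa2 in 1.85%, Gata6 in 1.79%, Hoxb4 in 1.27% and Hoxb1 in 0.284%. At 0 h and without RA, Rarb was found in 0.462% and 0.829%, Hoxa5 in 0.048% and 0.036%, and Cyp26a1 in 0.016% and 0.054%. In the thinned cells, Hoxb2 had no UMI at 0 h (1-sided upper limit 0.048%) and Hoxb1 none without RA (1-sided upper limit 0.054%), while without thinning 2 cells and 1 cell had one. With each cell's UMIs in full, at unequal depth, Stra8 was found in 92.5% of the RA cells, Rarb in 37.8%, Hoxa5 in 29.0% and Cyp26a1 in 11.1%. RNA released from other cells of the RA library was not measured, so these shares have no background of their own library.

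Pluripotency and formative genes were spread over the cells in other proportions. Nanog was found in 73.1%, 37.4% and 59.5% of cells at 0 h, without RA and with RA, Pou5f1 in 84.1%, 49.1% and 78.3%, Esrrb in 50.1%, 32.2% and 36.7%, and Zfp42 in 95.3%, 92.2% and 92.4%. Otx2 was found in 1.11%, 35.8% (34.6 to 37.1) and 2.93%, Pou3f1 in 2.12%, 28.8% and 5.26%, and Dnmt3b in 23.0%, 52.3% and 21.5%. Cdx1 was found in 17.6%, 0.451% and 19.9%, Meg3 in 28.3%, 26.4% and 2.24%, and Dazl in 2.31%, 5.86% and 15.8%. A median of 7, 5 and 5 naive genes and 0, 2 and 1 formative genes were found per cell. The medians were 1, 1 and 2 for RA pathway genes and 0 in each library for Hoxa and Hoxb genes. With RA, 72.5% of cells had no Hoxa UMI and 91.8% no Hoxb UMI, against 97.7% and 95.8% at 0 h.

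**Figure D4:**
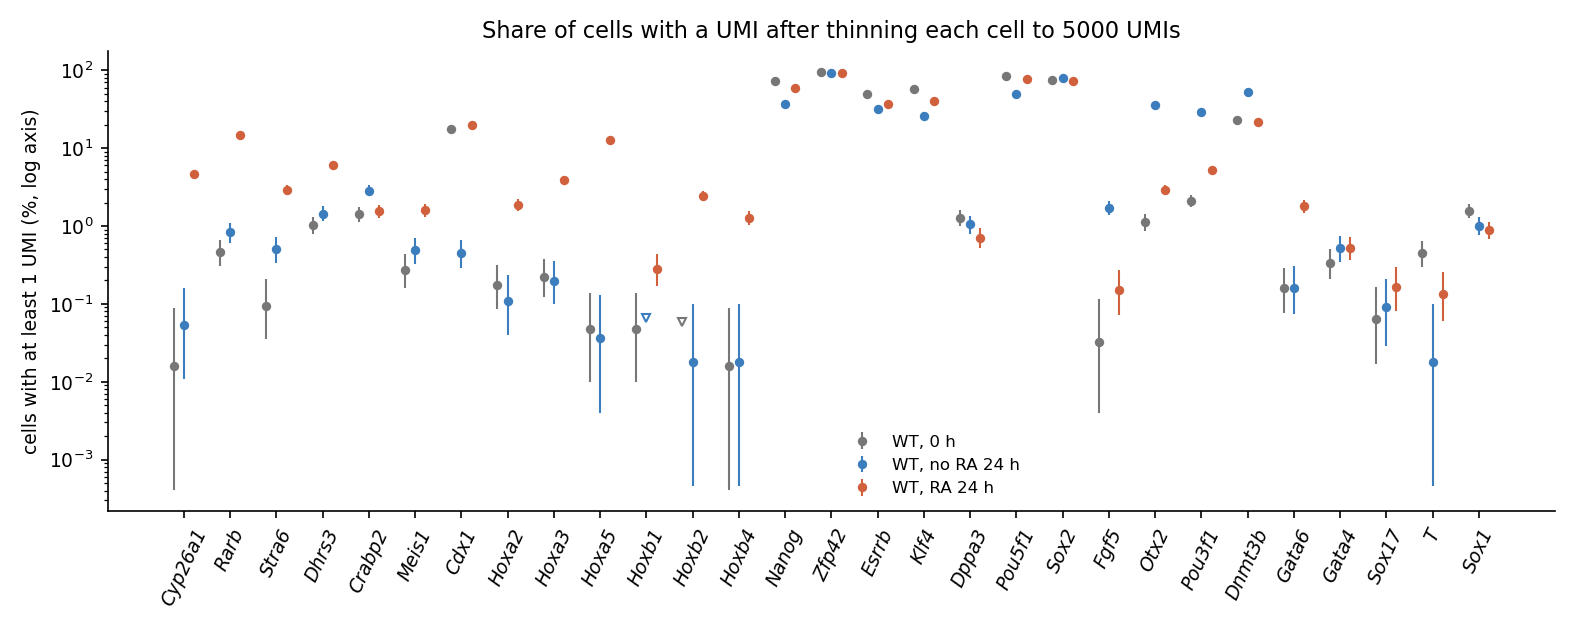
Percent of cells with at least 1 UMI (log axis) of genes with a planned share at 0 h, at 24 h without RA and at 24 h with RA, in cells thinned to 5000 UMIs, with exact 2-sided 95% binomial intervals and open triangles at their upper end where 0 cells had a UMI. Rarb was found in 0.462%, 0.829% and 14.9% of cells.

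Pairs of genes were compared with the number of cells that their shares give. With RA, Cyp26a1 and Nanog were found together in 151 cells, below the expected number (ratio 0.827, 0.701 to 0.968). The Gata6-led cluster described below had higher Cyp26a1 and lower Nanog. The ratio was not taken without its cells, so it does not show that the genes avoid each other within other cells. The interval of Cyp26a1 with Rarb (51 cells, 1.12, 0.833 to 1.47) included 1. Hoxb1 was found with Hoxb2 in 8 cells and with Cyp26a1 in 6, where 0.460 and 0.871 were expected, which is too few for a ratio. Without RA, Nanog and Otx2 were found together in 657 cells (0.884, 0.821 to 0.95), against a ratio of 0.996 at 0 h and 0.832 (0.675 to 1.01) with RA. Zfp42 and Dnmt3b had ratios of 1.02, 0.986 and 1.01 at 0 h, without RA and with RA.

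Clustering of each library alone gave 8 clusters at 0 h, 6 without RA and 6 with RA, some of them led by histone or cell-cycle genes. In each library the cluster with the highest median log2 ratio of the p53 list, among clusters of at least 100 cells, was singled out. It held 360 cells at 0 h (5.55%), 717 without RA (11.5%) and 727 with RA (10.3%). The medians over the list were 1.51, 2.09 and 1.95, with 8 of 10 members higher in each. These values follow in part from that choice and are no separate result. Perp, outside the list and picked after the leading genes were seen, was at 40.2 against 3.21 CPM at 0 h, 20.3 against 1.04 without RA and 22.1 against 2.02 with RA. In each library gene models without a name led that cluster, and members of the 2-cell-like (2 of 2 at 0 h, 4 of 4 without RA and 6 of 7 with RA), germline (5 of 11, 5 of 11 and 2 of 11) and endoderm lists (4 of 8, 3 of 8 and 9 of 15) were higher in it. A list gene was measured here with at least 1 CPM in a cluster or in the other cells. A gene low in the other cells could thus enter only by being high in the cluster, so these counts are no separate result. Few cells carried the 2-cell-like genes, with Zscan4d in 0.833% of the cluster's cells at 0 h, 1.26% without RA and 5.37% with RA. In the RA library the cluster also held Cyp26a1 at 37.9 CPM against 8.29 in the other cells, Gata6 at 46.7 against 2.51 and Zscan4d at 44.8 against 0.578. With the cell-cycle lists left out of the variable genes, the RA cluster with the highest p53 median had Zscan4d lower, at 0.419 against 5.16 CPM. At resolution 1, looked at more closely after these values were seen, the RA library split into 11 clusters, with Gata6 and Zscan4d highest in separate ones. There, the cluster with the highest p53 median at 0 h had 1 of 10 germline, 1 of 8 endoderm and 1 of 1 2-cell-like genes higher. Of 28 cells in a germline-led cluster at 0 h, 24 came from the 360 cells. With RA, 0 of 11 germline, 0 of 11 endoderm and 0 of 3 2-cell-like genes were higher. Without RA, 4 of 11, 2 of 7 and 4 of 4 were.

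At that resolution 589 RA cells (8.36%, 7.72 to 9.03) had higher p53 targets (9 of 10, median 2.17), with Trp53inp1 at 127 against 15.6 CPM and Cyp26a1 at 8.99 against 11.3. A cluster of 398 cells (5.65%, 5.12 to 6.21) was led by Gata6, Id2, Hoxb2, Lefty1, Meis1, Cyp26a1, Lama1, Id1, Lamb1 and Lefty2. It had 10 of 15 endoderm genes higher (median 1.64), 9 of 10 Hoxb genes higher (median 2.06) and 5 of 15 naive genes lower, with Nanog at 108 against 245 CPM, while Zfp42, at 380 against 732, was less than 2-fold lower. By the fixed markers it resembled extraembryonic endoderm, but it was led by Hox and RA genes as well, with Cyp26a1 at 57.5 against 8.08 CPM (7.12-fold, 6.31 to 8.02), Hoxb1 at 7.58 against 0.335 and Hoxa5 at 70.2 against 27.0. Stra8, at 638 against 449 CPM, and Rarb, at 47.5 against 35.5, differed less. Another cluster of 83 cells (1.18%, 0.939 to 1.46) had the 9 measured genes of the 2-cell-like state higher, with Zscan4d at 385 against 0.450 CPM, Zscan4c at 219 against 0.335 and Nanog at 589 against 232. In these cells 5 of 9 p53 targets were higher as well (median 1.08), and 71 of them came from the cluster with high p53 targets at resolution 0.5. Such folds describe genes that helped to build the clusters.

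**Figure D5:**
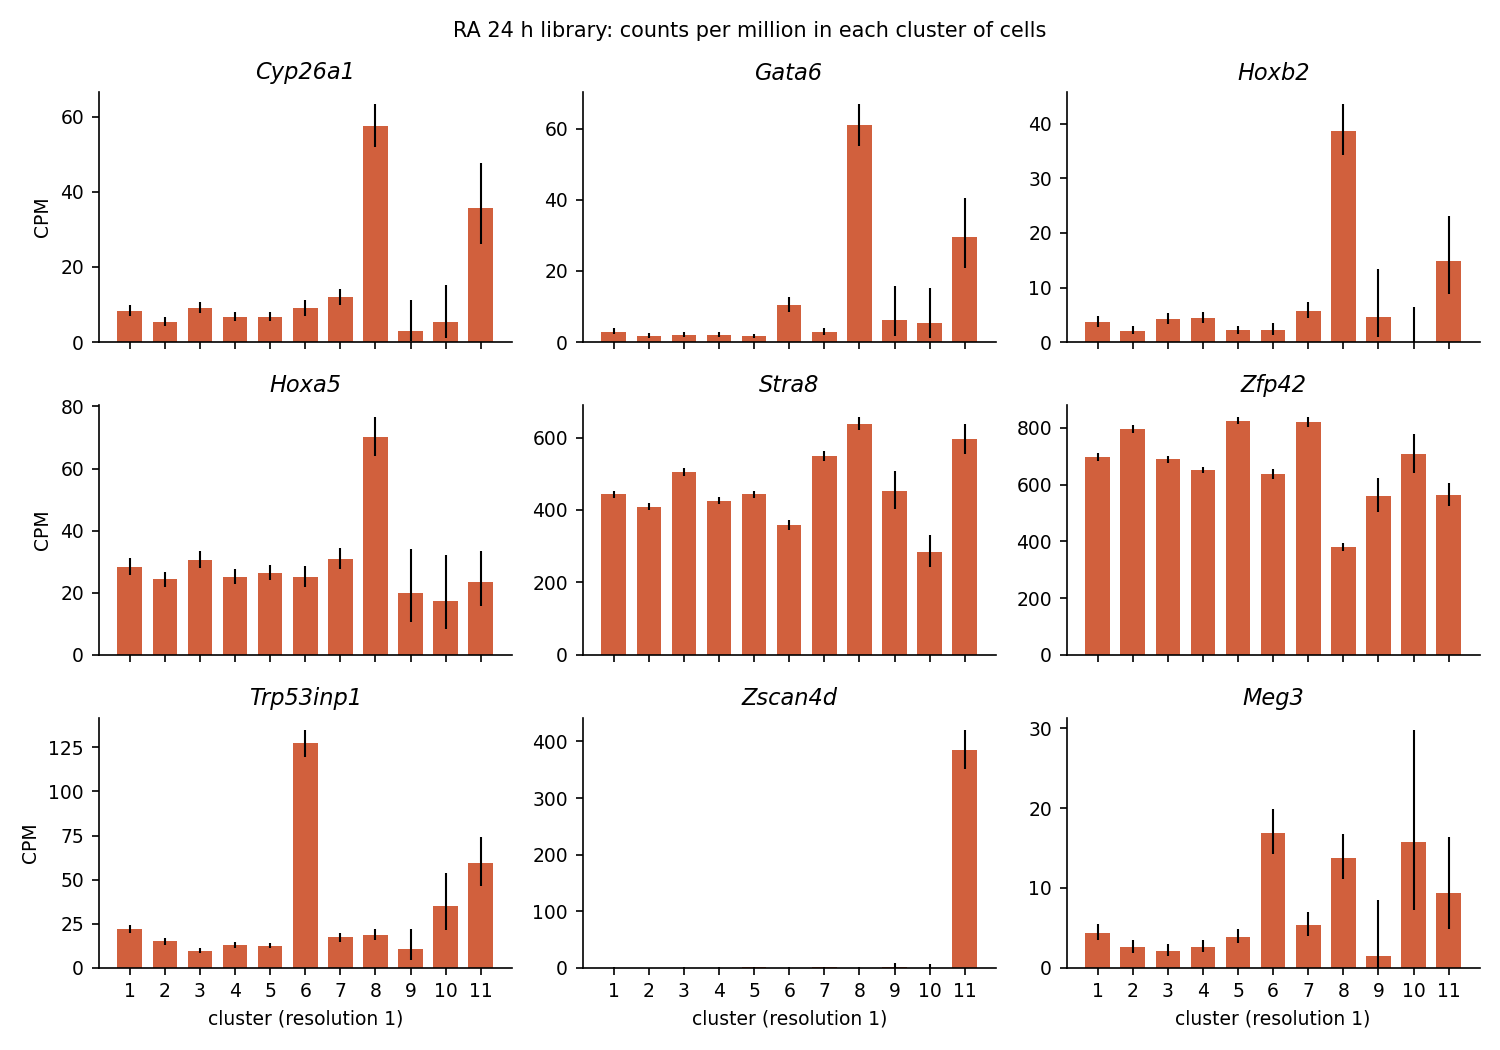
CPM with exact Poisson 95% intervals (y axis) of 9 genes in the 11 clusters of the RA library at resolution 1 (x axis). Gata6 was at 60.9 CPM in the cluster it leads and 3.16 in the other cells, and Zscan4d at 385 and 0.450 for the cluster with genes of the 2-cell-like state.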

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

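The removal of the 6% of cells with the highest doublet scores and the clustering without RA, Hox, caudal, endoderm and share genes were chosen only after the results were seen. Removal of doublets called by Scrublet, which had been planned, was not run, since its threshold marked at most 1 cell, and no library could be left out with 1 per group. Medians of lists without a clear direction changed sign under some scalings, filters, pseudocounts or measurement floors. Single genes were followed only where named. The 195 named differences of at least 2-fold kept their direction under each of 8 scalings, cell filters and pseudocounts, and 182 of them (TMM), 190 (means of per-cell CPM), 192 (all barcodes, or totals without mitochondrial and ribosomal protein genes), 193 (stricter filter), 194 (6% removal), 195 (pseudocount 0.1) and 140 (pseudocount 5) remained at least 2-fold. A pseudocount cannot change a direction. TMM factors (log2 shift -0.141 without RA against 0 h) and totals without mitochondrial and ribosomal protein genes (-0.034) moved ratios too little to reverse a 2-fold difference. Only the choices of cells and the means of per-cell CPM could have reversed a direction. Under the 8 settings the counts ranged over 181 to 296 higher and 76 to 144 lower genes without RA against 0 h, 217 to 344 and 127 to 219 with RA against 0 h, and 97 to 157 and 106 to 158 with RA against no RA. Each kind of value had its own rule for having moved. Counts that changed by over 1.5 times were 18 of 66 gene counts, 89 of 729 counts of list members and 2 of 15 cluster numbers. Values that moved by more than their interval were 637 of 3440 log2 ratios of named genes, 230 of 450 shares of cells and 4 of 78 ratios of pairs. A set step on the log2 scale was reached by 74 of 714 list medians. The quartiles over cells were left by 11 of 75 medians of list genes per cell. In the order no RA against 0 h, RA against 0 h and RA against no RA, a floor of 5 CPM gave 525, 627 and 261 higher and 202, 297 and 273 lower genes, a floor of 50 CPM gave 120, 123 and 51 higher and 52, 73 and 66 lower, and no floor beyond 1 CPM gave 713, 904 and 383 higher and 279, 364 and 338 lower, because the floor sets how many genes are counted. With a pseudocount of 5 CPM, which shrinks ratios of low genes, 7 formative genes and 1 RA pathway gene were higher and 0 Hoxb genes lower without RA against 0 h, 2 formative, 4 Hoxa and 1 Hoxb genes were higher with RA against 0 h, and 4 Hoxa and 1 Hoxb genes with RA against no RA. With a pseudocount of 0.1 CPM, 2 Hoxb genes were lower without RA against 0 h, and 8 formative and 8 Hoxb genes higher with RA against 0 h. With list members measured at 10 CPM, which leaves fewer genes, 1 RA pathway gene was higher and 0 Hoxb genes lower without RA against 0 h, and 3 Hoxa and 0 Hoxb genes were higher with RA in both comparisons. With TMM scaling, 1 RA pathway gene was higher without RA against 0 h. Depth limits the shares: Cyp26a1 was found in 3.14% of RA cells thinned to 3000 UMIs, 6.91% at 8000 and 11.1% without thinning. Resolution sets cluster numbers, with 5 clusters at 0 h at resolution 0.3 and 11 with RA at resolution 1.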

Other observations

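The tests of Meg3 and Rian in single cells, and of doublets and dissociation stress in the clusters with high p53 targets, were chosen only after the results were seen, as were both patterns weighed below. The bounds for cells with both Meg3 and Rian were replaced after the ratio was seen, where an earlier bound of 5 would have been met, and the doublet test was replaced after the shares of high doublet scores were seen.

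Of 6 other genes at or near the imprinted locus that holds Meg3, 2 were also low in the RA library. Mirg was at 0.881 CPM with RA against 12.3 without RA and 10.3 at 0 h, and Rtl1 at 0.209 against 3.03 and 2.23, while Dlk1 was at 1.30 against 0.378 and 0.398, Dio3 at 0.628 against 0.609 and 1.60, Begain at 0.794 against 0.548 and 0.329, and Wdr25 at 11 against 13.1 and 10.8. Of 16 other imprinted genes measured, 1 was at least 2-fold higher with RA than without, Plagl1 (2.20 against 0.317 CPM, and 4.72 at 0 h), and 0 were lower. The imprinted RNA Snhg14, tested with the nuclear noncoding RNAs, was lower with RA than without (22.1 against 46.4 CPM), but was at 12.9 at 0 h. At resolution 1, 604 cells without RA and 189 cells at 0 h formed clusters with Chac1, Vegfa, Ddit4 and Stc2 among their leading genes, which respond to amino acid shortage or low oxygen. With RA, a cluster of 511 cells had Chac1 and Stc2 among its leading genes, but not Vegfa or Ddit4. At 0 h, 28 cells were led by Scml2, Stra8 and Asz1, germline genes. In the RA library, Scml2 (99.6 against 4.07 CPM) and Asz1 (21.8 against 1.13) were also higher in the 83 cells with genes of the 2-cell-like state than in the other cells.

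Meg3 and Rian, neighbours on chromosome 12 (109541001 to 109571726 and 109603940 to 109661716), were lower in the RA library. Less capture of nuclear RNA as the whole cause is argued against by 6 other nuclear noncoding RNAs. Their median log2 ratio against no RA was -0.623, where -2 or less was needed. It lay below the median of -0.016 over all measured genes, so a smaller part played by capture stays open. Loss of a chromosome copy over the wider region is argued against by 49 genes within 10 Mb, with a median of -0.074. The genes nearest to Meg3 were left out of these, so a smaller loss at the locus itself was not tested. A mixture would have a few percent of the RA cells keep the level and the rest have none. It cannot be told apart from an uneven lowering. Both RNAs were found in 21 cells where 2.598 were expected, an excess of 8.083-fold (5.01 to 12.3) that rests on few expected cells. That ratio lay above those at 0 h (1.46) and without RA (1.51). It lay below the 17.1 that a mixture of 8.78% needs if the other cells add no UMI, and released RNA was not measured. The levels were uneven among RA cells, with Meg3 at 20.8 against 3.5 CPM (5.96-fold, 5.02 to 7.05) and Rian at 11.4 against 2.80 (4.09-fold, 3.29 to 5.07) in the cluster with high p53 targets and in the other cells. At resolution 1, 160 cells of that cluster fell in the Gata6-led cluster and 71 in the one with 2-cell-like genes. The excess is thus not tied to high p53 targets alone. In the like clusters Meg3 was lower than in the other cells at 0 h (69.3 against 78.2 CPM) and without RA (59.5 against 80.0). An effect of RA or its medium on the locus and a difference between cultures may each account for the pattern. Both stay open and untested with 1 library analysed per condition.

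Each library held a cluster of cells with high p53 targets. Doublets, which hold the RNA of more than 1 cell, are argued against by median UMIs of at most 0.931 times those of the library (0.88 to 0.975) at resolutions 0.5 and 1, while the share of cells among the 6% with the highest doublet scores was 2.5% to 4.05% at resolution 0.5 and, with RA at resolution 1, 6.79% (4.90 to 9.13). Stress of dissociation cannot be told apart from a state present in the culture: the median log2 ratio of the stress list was 0.307 with RA, below the bound of 0.5 that argues against it, 1.01 without RA, above the bound of 1 that it needs, and 0.765 at 0 h, so the libraries differ. In the RA library, Cyp26a1 could seem higher in that cluster only because it helped to build it; with RA, Hox, endoderm and share genes left out of the clustering it was still 2.095-fold higher (1.78 to 2.45), below the bound of 2 by its lower end, so this too cannot be told apart. At the finer resolution, where cells with Gata6 formed their own cluster, Cyp26a1 was at 8.99 CPM in the cells with high p53 targets and 11.3 in the others.

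In the RA library, pairs chosen after the values were seen included Hoxa5 with Hoxa3 (ratio of observed to expected cells 2.17, 1.71 to 2.72), Hoxa5 with Hoxb2 (2.34, 1.74 to 3.10), Cyp26a1 with Hoxa5 (1.79, 1.40 to 2.26), Hoxa5 with Rarb (1.04, 0.869 to 1.23), Gata6 with the p53 target Trp53inp1 (2.02, 1.32 to 2.95) and Cyp26a1 with Trp53inp1 (1.24, 0.892 to 1.68). Cyp26a1 and Gata6 had a ratio of 4.18 (2.65 to 6.27), and 3 cells with both, too few for a ratio to be given, were left without the endoderm-like cells. Both genes are leading genes of that cluster, so its removal takes out cells with both and is no separate result. Hoxb2 is a leading gene of the same cluster, and Hoxa5 was higher in it. Its cells may therefore add to the ratios of Hoxa5 with Hoxb2 and with Cyp26a1, which were not taken without them.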
